A study of Mus musculus with 4 samples.

How the data were processed

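RIP-seq libraries of sorted CD31-positive cells from the caudal part of wild-type mouse embryos at embryonic day 10 were compared, 2 made with an antibody against Runx1 and 2 with IgG. Per the labels' protocols, antibodies were held on protein A beads, the recovered RNA went into a reverse transcription reaction devised for single cells, and the cDNA was sheared by sonication before the libraries were built. Such a protocol amplifies very small amounts of RNA without molecular identifiers named in the labels, so that intervals and floors given for counts cover counting error only. The groups and replicate numbers came from the sample titles.

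The authors deposited a single table of raw counts per Ensembl gene, as whole numbers with no normalization, with 1 column per library. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.7.3a, Salmon 1.1.0 and the mm10 build were used, with no role or order stated. The gene annotation, the strand setting, any filter and whether the whole numbers are counted reads or rounded estimates are not given in the sources used here. Rounded estimates would divide reads between similar genes, while counting would drop or share them, which matters most for the ribosomal protein genes. The table held 55573 gene identifiers, of which 55480 were found in the GENCODE M21 annotation of the same build and 93 were not, and 92 spike-in rows from the ERCC set, synthetic RNAs added to a sample in known amounts. The amount added and the step of addition are not given in the sources used here. Spike-in rows were kept out of library sizes and tests. All 4 columns of values were mapped to a library by name.

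Gene counts per library were 1675488 and 1887301 with the Runx1 antibody and 3843318 and 2482045 with IgG, so that 3 counts correspond to 1.79, 1.59, 0.781 and 1.21 CPM. Levels are CPM of the gene total. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM normalization, filterByExpr defaults with a minimum count of 10 and a minimum total of 15) over all 4 libraries with no block, two-sided, and p-values were adjusted by Benjamini-Hochberg over 12401 genes at a false discovery rate of 0.05. Log2 fold changes are given with the standard error implied by the test statistic. Lists of genes, 30 in all, were written before the data were examined and tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and fry beside it. They cover RUNX proteins and cofactors, blood, endothelial and transition genes, markers of erythroid, megakaryocyte, macrophage, mesenchymal, epithelial and neural cells, RNA classes, and groups of cell biology. Intervals of list medians come from 2000 bootstrap draws over genes. Whole-library measures were compared by an exact permutation test of 2 against 2 libraries, which has 6 arrangements and cannot give a two-sided p below 0.333.

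The rule for named genes was also fixed before the data were examined. It took up to 12 higher and up to 12 lower genes with the largest fold change among those that passed, whose libraries do not overlap between antibodies and whose mean is at least 10 CPM, leaving out pseudogenes, predicted genes and unnamed identifiers. It added up to 4 members per list with the smallest p, and always Runx1, Cbfb, Gata2, Gfi1, Pecam1, Cdh5, Kit, Ptprc, Malat1 and Neat1. CT010467.1 carries a clone name and was treated as an unnamed identifier, a reading made after its values were seen; other genes named outside the rule are said to be so.

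Transcript length, GC content, 3′ UTR length and exon overlap came from the annotation, with the longest transcript standing for each gene. Near-identical copies were found with blastn 2.17.0 as stretches of at least 200 bases at 95% identity or more in the transcripts of other genes. The alternatives chosen before the data were examined were DESeq2 size factors, library totals alone, no low-count filter, a strict filter of 10 counts in all libraries, a replicate block, each library left out in turn, removal of mitochondrial and haemoglobin genes, DESeq2 1.42.0, limma-voom, a null of 1.5-fold, a looser threshold of 0.1, and other folds and scalings of the descriptive count. Scaling to the spike-ins, random thinning of all libraries to the smallest total, and a correction for length and GC content (natural splines with 5 degrees of freedom per library, as offsets) were added after seeing the data. The spike-in scaling was run for the gene test and for fold changes and list medians, with no list test, since one factor per library leaves the differences between genes almost as they were.

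The gene test was tested on counts simulated from the means and library sizes of the 12401 genes, of which 11638 passed the filter. The genes set to change that passed numbered 48 at 1.5-fold, 46 at 2-fold, 48 at 3-fold and 43 at 4-fold. The test recovered 0% of genes changed 1.5-fold, 4.35% of those changed 2-fold, 25% at 3-fold and 34.9% at 4-fold, and called 0 unchanged genes. Among the fewer of these with a mean of at least 100 CPM, the shares called, with no condition on sign, were 0%, 20%, 80% and 80%. In the simulated lists the shifted list passed (camera adjusted p = 2.32e-10) and 0 unshifted lists did. Genes were drawn independently of each other, so this cannot show how camera with the preset correlation behaves where genes vary together. A simulated length slope of -0.30 went to -0.016 after the correction.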

Results

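RUNX1 is a transcription factor that blood stem and progenitor cells need in order to form from the endothelium of the embryo. RNA immunoprecipitation sequencing (RIP-seq) recovers and sequences the RNA held on beads by an antibody against a protein. The same procedure with a non-specific antibody (IgG) measures the background. Here, cells carrying CD31 (Pecam1), a surface protein of endothelial and some blood cells, came from the caudal part of wild-type mouse embryos at embryonic day 10. There were 2 libraries made with an antibody against Runx1 and 2 made with IgG. A library of the input RNA was not analysed here. The libraries held 1675488 and 1887301 gene counts with the Runx1 antibody and 3843318 and 2482045 with IgG. Between 16929 and 18401 genes had at least 1 count in a library. The question was which RNAs were recovered more with the Runx1 antibody than with IgG. Higher and lower below mean a larger or smaller part of the library relative to the typical gene, since the amount of RNA recovered per pull-down is not part of a count table. Nothing in the labels says that the replicates came from separate embryos or sorts, so the p-values measure the spread between these libraries, which may be technical.

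Messenger RNAs of the translation machinery and the cytoskeleton were among the 38 genes that were higher with the Runx1 antibody. Under the spike-in scaling described below, 6 of the 38 stayed above 0 and 0 were called higher. Eef1a1, which brings aminoacyl-tRNAs to the ribosome, stood at 7238 ± 93.3 CPM (counts per 1e6 gene counts, mean ± SD, n = 2) against 3681 ± 164 with IgG. Its log2 fold change was 0.95 ± 0.065 (SE, edgeR adjusted p = 0.00249). Eif5b, a factor that joins the ribosomal subunits, stood at 6516 ± 285 against 2991 ± 312 CPM (log2 fold change 1.09 ± 0.085, edgeR adjusted p = 0.00370). The polyubiquitin gene Ubb rose 3.48-fold (559 ± 64.1 against 158 ± 12.2 CPM, edgeR adjusted p = 0.00858). Rplp0, a protein of the ribosomal stalk, rose 3.04-fold (1011 ± 125 against 326 ± 48.7 CPM, edgeR adjusted p = 0.00961). Tropomyosin Tpm3 rose 2.63-fold, Rpl8 2.55-fold, Ccdc34 2.42-fold, and beta-actin Actb 2.38-fold. Rpl6 rose 2.36-fold, the imprinted non-coding RNA H19 2.35-fold, beta-tubulin Tubb5 2.29-fold, Rpl4 2.19-fold, ferritin light chain Ftl1 2.18-fold and Rps3 2.17-fold. Over these genes the edgeR adjusted p ran from 0.00858 (Ccdc34, Rpl4) to 0.0490 (Rps3). The gene with the largest rise, singled out after its values were seen, was CT010467.1, annotated as ribosomal RNA on chromosome 17 (39846353 to 39848827). It stood at 102 ± 0.61 against 19.6 ± 0.81 CPM (log2 fold change 2.35 ± 0.39, edgeR adjusted p = 0.0470). After the length and GC correction described below, 8 of these genes were no longer called. Tpm3 (log2 fold change 1.23 ± 0.22) stayed within its SE of the main value, while CT010467.1 (1.93 ± 0.39), Actb (0.95 ± 0.19), Rps3 (0.91 ± 0.20), Rpl6 (0.88 ± 0.19), H19 (0.85 ± 0.17), Rpl8 (0.81 ± 0.16) and Ftl1 (0.57 ± 0.17) moved by more.

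The genes that were lower with the Runx1 antibody included Cbfb, which encodes the partner that RUNX proteins bind DNA with. Cbfb stood at 156 ± 8.34 CPM against 348 ± 3.52 with IgG, a log2 fold change of -1.19 ± 0.19 (edgeR adjusted p = 0.0432, n = 2 and 2). Ptbp2, a regulator of splicing, stood at 491 ± 27.4 against 1160 ± 13.6 CPM (log2 fold change -1.27 ± 0.12, edgeR adjusted p = 0.00858). Mib1, a ubiquitin ligase that acts on Notch ligands, stood at 288 ± 52.8 against 722 ± 21.8 CPM (log2 fold change -1.36 ± 0.17, edgeR adjusted p = 0.0209). The log2 fold change was -1.86 for the phosphatase gene Cdc14a, -1.64 for Scai, -1.31 for the aminopeptidase gene Lnpep, and -1.29 for Zfp871 and for Fam199x. It was -1.24 for the O-GlcNAc transferase gene Ogt, -1.21 for Lrrc58 and -1.20 for Trove2, which encodes the Ro RNA-binding protein. The edgeR adjusted p of these genes ran from 0.0159 (Zfp871) to 0.0417 (Scai). The T-box gene Tbx15 had 1 and 2 counts with the Runx1 antibody and 114 and 77 with IgG. The IgG libraries held 35.9 times more of it per count sequenced (exact 95% interval 12.1 to 175, counting error only, edgeR adjusted p = 0.0490). Only Ptbp2 of these lower genes was still called after the length and GC correction. Cbfb (-1.08 ± 0.20), Cdc14a (-1.65 ± 0.27) and Tbx15 stayed within their SE of the main value, so that their lost calls do not point to length or GC. The others shrank, to between -0.57 (Trove2) and -0.93 (Scai).

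In the mm10 (GRCm38) annotation, Eef1a1 lies on chromosome 9 (78478449 to 78489151), Eif5b on chromosome 1 (37998010 to 38055579) and Ubb on chromosome 11 (62551171 to 62553213). Rplp0 lies on chromosome 5 (115559467 to 115563727) and H19 on chromosome 7 (142575529 to 142578143). Among the lower genes, Cbfb lies on chromosome 8 (105170674 to 105217989), Ptbp2 on chromosome 3 (119718742 to 119784466), Mib1 on chromosome 18 (10725548 to 10818704) and Tbx15 on chromosome 3 (99240381 to 99354259). Other genes carry near-identical stretches of Eef1a1 (9 genes), Ftl1 (7), Rpl6 (4), Rplp0 (4), Ubb (2), and of Rpl4, Rps3, Tpm3, Lrrc58 and Eif5b (1 each). The same holds for called genes named below, Rpl3 (7), Rps4x (7), Actg1 (6), Hspa8 (6), Hsp90aa1 (3), Eno1 (3) and mt-Co1 (2). Copies of CT010467.1 were not looked for. Exons of H19, Ftl1, CT010467.1, Rpl4, Rpl6, Rps3, Eef1a1, Eif5b, Lrrc58 and Cdc14a overlap other genes. Their values are uncertain to the extent that counting could split or share reads.

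Of 12401 genes tested, 38 were higher and 42 lower with the Runx1 antibody at an edgeR false discovery rate of 0.05. The median change was 2.03-fold up and 2.10-fold down, and 76 of the 80 were protein-coding. All 80 had both Runx1 libraries on one side of both IgG libraries, as did 45.4% of all tested genes, where chance gives 33.3%. The calls, made with 4 libraries and a biological coefficient of variation of 46.1%, lay almost wholly among abundant RNAs. A mean of at least 100 CPM was reached by 78 of the 80 and by 2381 of the tested genes. At an unadjusted edgeR p under 0.05 there were 853 higher and 913 lower genes. The count of calls moved with each library, to 248 higher and 352 lower without Runx1 replicate 1, and 161 and 220 without Runx1 replicate 2. It moved to 114 and 85 without IgG replicate 1, and 95 and 81 without IgG replicate 2. In all 4 of these fits 36 of the 38 and 37 of the 42 were called. With a replicate block in the edgeR fit 2 genes were higher and 0 lower (1566 at an unadjusted p under 0.05), though nothing in the labels says that the replicate numbers pair the libraries. Against a null of a change under 1.5-fold (glmTreat in edgeR), 0 genes passed, with 880 at an unadjusted p under 0.05. Against a null of no change DESeq2 called 246 higher and 344 lower and limma-voom 102 and 120. Scaling to the spike-in RNAs, chosen after seeing the data, moved most genes down by similar amounts, the median gene from 0.027 to -1.25 (log2). It gave 19 higher and 3914 lower genes, among them 0 of the 38 and 42 of the 42. A correction for transcript length and GC content, also chosen after seeing the data, gave 22 higher and 6 lower, among them 16 and 4 of the main calls. Of the 22 higher and 38 lower calls that ended, 1 and 5 moved by less than their SE. The median size of the ended calls went from 1.03 to 0.68 and from 1.07 to 0.62, with little change in their SE.

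**Figure D1:**
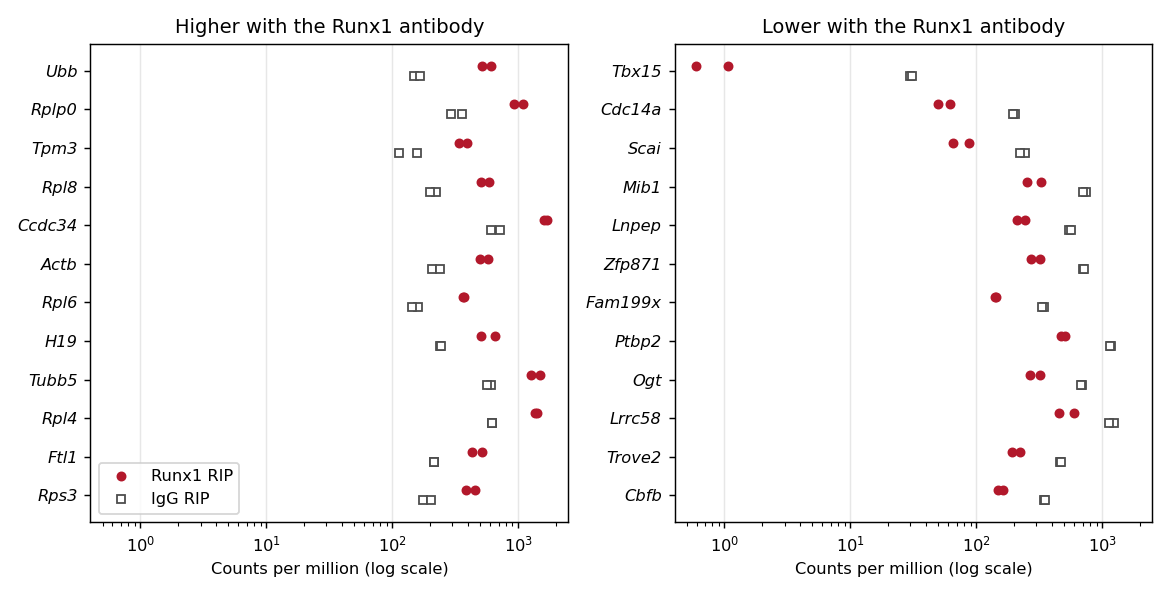
CPM (horizontal log axis) of the 12 higher and 12 lower genes named by the fixed rule, with each Runx1 antibody library as a filled circle and each IgG library as an open square. In every gene shown the 2 libraries of each antibody lie apart from those of the other. Under the spike-in scaling 5 of the 12 higher genes (Ubb, Rplp0, Tpm3, Rpl8 and Ccdc34) stay above 0. With that scaling 0 of the 12 are called higher (edgeR adjusted p of the 5 from 0.226 to 0.976).

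Among the gene lists fixed before the data were examined, 8 of 30 were higher relative to other genes by camera with a preset correlation. By camera with an estimated correlation 0 were (2 at an unadjusted p under 0.05). Under the spike-in scaling, which moves most genes almost alike, all 30 list medians were below 0. Relative to the median gene under that scaling, the medians of the 8 lists stayed at 0.34 to 0.81. The range given after a list median is the one over the other settings, spike-in scaling aside. No list was lower by camera (0 at an unadjusted p under 0.05) or by fry (1 at an unadjusted p under 0.05, the RUNX1 cofactors). With fry the ribosomal protein and cell cycle lists passed. The list of cytosolic ribosomal proteins had the smallest p, and 77 of its 80 measured genes had a fold change above 1, though the list median was -0.44 under the spike-in scaling (0.81 relative to the median gene). In edgeR 8 of the 80 rose, 0 fell and 72 did not pass (27 higher and 0 lower with DESeq2, 17 and 0 with limma-voom), with 33 higher when adjusted over the list alone. Their median log2 fold change was 0.83 (95% bootstrap interval 0.75 to 1.01, range 0.52 to 0.90), with a camera adjusted p of 2.67e-17 and an adjusted p of 0.296 with an estimated correlation. The 8 were Rplp0, Rpl8, Rpl6, Rpl4, Rps3, Rack1 (1.02), Rpl3 (1.01) and Rps4x (0.92), with log2 fold changes in brackets, of which Rplp0 and Rpl4 were still called after the length and GC correction and the others stood at 0.60 to 0.91. Translation factors had a median of 0.36 (range 0.24 to 0.43, and -0.91 under the spike-in scaling) over 65 genes, of which in edgeR 3 rose (Eef1a1, Eif5b and Eif3a, 0.68 ± 0.084), 0 fell and 62 did not pass. There were 5 higher when adjusted over the list alone, 9 higher and 1 lower with DESeq2, 4 and 0 with limma-voom, and 17 and 4 at an unadjusted edgeR p under 0.05. Their camera adjusted p was 0.0273 (adjusted p = 0.466 with an estimated correlation). The call was lost with each of the 4 libraries left out in turn (adjusted p over all settings 0.0141 to 0.466). Ribosome biogenesis factors had a median of 0.45 (range 0.16 to 0.47) over 31 genes and did not pass (camera adjusted p = 0.123, or 0.0443 to 0.715 over the other settings). The lowest of these, without Runx1 replicate 1, would pass. The nucleolar protein gene Ncl rose (0.54 ± 0.072, edgeR adjusted p = 0.0240), 0 fell, 30 did not pass, and 2 were higher adjusted over the list alone (3 with DESeq2, 2 with limma-voom).

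Of the lists of energy metabolism, oxidative phosphorylation, mitochondrially encoded mRNAs and glycolysis were higher relative to other genes by camera with a preset correlation. Each of these calls was lost with an estimated correlation, and each median was below 0 under the spike-in scaling (0.50 to 0.73 relative to the median gene). The 63 measured nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of 0.77 (-0.53 under the spike-in scaling), and 56 of them were above 0. Without Runx1 replicate 2 the median of the nuclear-encoded oxidative phosphorylation list was 0.47, and after the length and GC correction 0.29, and the list passed in both. Their camera adjusted p was 5.23e-07 (adjusted p = 0.296 with an estimated correlation). None of the 63 passed alone in edgeR, over all genes or adjusted over the list alone. There were 9 higher at an unadjusted p under 0.05, 2 higher with DESeq2 and 1 with limma-voom. The subunit genes Atp5b (0.60 ± 0.14) and Atp5c1 (2.01 ± 0.46) came nearest, each with an edgeR adjusted p of 0.102. All 8 measured mitochondrially encoded mRNAs had a fold change above 1 (median 0.67, range 0.55 to 0.85, and -0.60 under the spike-in scaling). Their camera adjusted p was 0.0137 (adjusted p = 0.609 with an estimated correlation). Of the 8, mt-Co1, a subunit of cytochrome oxidase, rose (2158 ± 200.1 against 1055 ± 61.8 CPM, edgeR adjusted p = 0.0120), 7 did not pass, and there were 5 higher adjusted over the list alone (4 with DESeq2, 3 with limma-voom). Of the mitochondrial ribosomal RNAs, mt-Rnr2 rose (1.11 ± 0.15, edgeR adjusted p = 0.0244) and mt-Rnr1 did not pass (0.31 ± 0.30). This list of mitochondrial tRNAs and rRNAs had 2 measured genes, a median of 0.71 (range 0.10 to 0.86), a camera adjusted p of 0.182 and 1 higher adjusted over the list alone. Glycolysis genes had a median of 0.52 over 18 genes (range 0.31 to 0.64, and -0.75 under the spike-in scaling), with a camera adjusted p of 0.00588 (adjusted p = 0.466 with an estimated correlation). The enolase gene Eno1 rose (1.09 ± 0.13, edgeR adjusted p = 0.0159, or 0.68 ± 0.14 and not called after the length and GC correction), 17 did not pass, and 7 were higher adjusted over the list alone (4 with DESeq2, 2 with limma-voom).

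Of 19 genes of the actin and tubulin cytoskeleton, 4 rose (Tubb5, Actb, Actg1 at 0.68 ± 0.11 and the intermediate filament gene Vim at 1.02 ± 0.17), 0 fell and 15 did not pass in edgeR. There were 8 higher adjusted over the list alone, 8 with DESeq2 and 6 with limma-voom. Their median was 0.68 (range 0.34 to 0.72, and -0.59 under the spike-in scaling), with a camera adjusted p of 5.77e-04 and an adjusted p of 0.518 with an estimated correlation. Genes that respond to tissue dissociation and stress had a median of 0.69 over 18 genes (-0.58 under the spike-in scaling), with a camera adjusted p of 0.0114 (adjusted p = 0.518 with an estimated correlation). Without Runx1 replicate 2 the median of these dissociation and stress genes was 0.28. In that list 2 chaperone genes expressed in most cells rose, Hsp90aa1 (0.75 ± 0.074, edgeR adjusted p = 0.00858) and Hspa8 (0.71 ± 0.12, edgeR adjusted p = 0.0438). Both were also called over the list alone, and the other 16 did not pass. Cell cycle genes had a median of 0.55 over 38 genes (range 0.33 to 0.58, and -0.76 under the spike-in scaling). Their camera adjusted p was 0.00405 (adjusted p = 0.466 with an estimated correlation) and their fry adjusted p 0.00930. No cell cycle gene passed alone over all genes in edgeR. There were 12 higher at an unadjusted p under 0.05, 5 with DESeq2, 2 with limma-voom and 3 adjusted over the list alone. The replication helicase gene Mcm6 stood at 1.11 ± 0.23 (edgeR adjusted p = 0.0797). Without Runx1 replicate 2 or without IgG replicate 1 the glycolysis and the stress lists no longer passed. Without Runx1 replicate 1 or IgG replicate 1 the mitochondrial mRNA list did not. After the length and GC correction the stress, translation factor, glycolysis and cytoskeleton lists no longer passed, and of the genes named in this paragraph Actb (0.95 ± 0.19), Actg1 (0.34 ± 0.11), Vim (0.67 ± 0.18) and Hspa8 (0.47 ± 0.13) were no longer called.

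**Figure D2:**
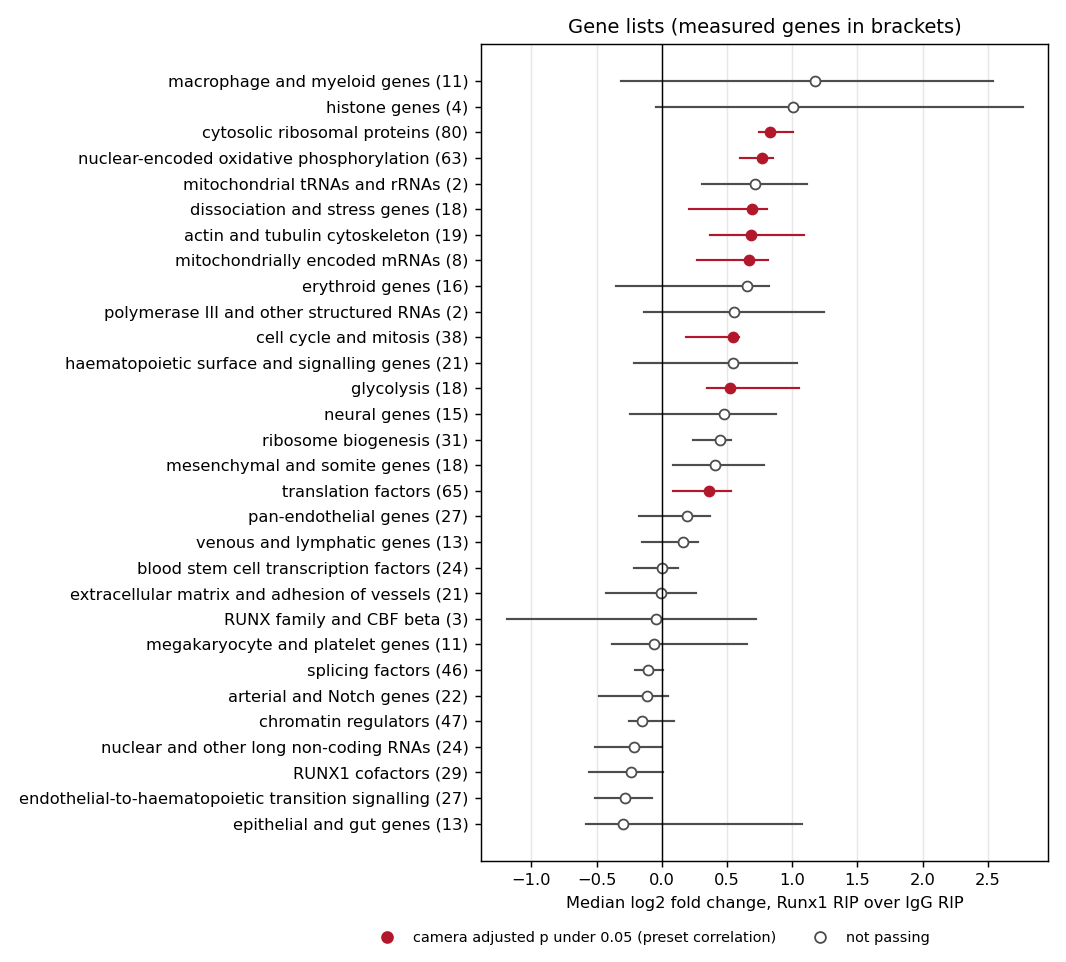
Median log2 fold change (Runx1 antibody over IgG, horizontal axis) of the measured members of each of the 30 gene lists, with the 95% bootstrap interval over genes as a line and the number of measured genes in brackets. Filled red points are the 8 lists that passed by camera with a preset correlation, with medians from 0.36 to 0.83, of which 0 passed with an estimated correlation, open points are the others, and under the spike-in scaling all 30 medians were below 0, with the 8 at 0.34 to 0.81 relative to the median gene.

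RUNX1's own transcript and its partners were examined as fixed lists. Runx1 RNA, on chromosome 16 (92601466 to 92826149, with exons overlapping genes of the opposite strand), stood at 32.2 ± 0.86 CPM with the Runx1 antibody and 19.2 ± 1.37 with IgG. Its log2 fold change of 0.72 ± 0.57 did not pass (edgeR adjusted p = 0.647). Runx2 stood at -0.047 ± 0.84. Of the 3 measured genes of the RUNX and CBF beta list only Cbfb passed, over all genes and over the list alone (median -0.047, range -0.65 to 0.63, camera adjusted p = 0.861). Among 29 genes of RUNX1 cofactors the median was -0.24 (range -0.28 to -0.15) (camera adjusted p = 0.157), and only Cbfb passed in edgeR, over all genes and over the list alone. The corepressor gene Ncor1 stood at 0.49 ± 0.15 and Tle4 at -0.61 ± 0.20, and neither passed in edgeR. Among the cofactors 1 was higher and 1 lower with DESeq2, 0 and 1 with limma-voom, and 1 and 4 at an unadjusted edgeR p under 0.05.

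The blood and endothelial programmes gave few calls, as did the tested genes as a whole (80 of 12401). In simulated counts the test recovered 4.35% of genes changed 2-fold, so a gene that did not pass may still differ. No transcription factor of blood stem cells passed among 24 measured (edgeR, with 1 higher and 0 lower at an unadjusted p under 0.05, 0 with DESeq2, limma-voom or over the list alone). Their median was 0.0035 (range -0.089 to 0.095) and their mean -0.063, with the camera test pointing down (adjusted p = 0.801). Gata2, which blood stem cells require, stood at 55.1 ± 5.29 against 54.6 ± 23.6 CPM (log2 fold change -0.019 ± 0.45). Gfi1, which encodes a repressor, was not tested, with a total of 1 count over the 4 libraries. Surface and signalling genes of blood cells had a median of 0.55 (range 0.10 to 0.69) over 21 genes (camera adjusted p = 0.155). Kit, the stem cell factor receptor gene, stood at -0.25 ± 0.41 and Ptprc, which encodes CD45, at -0.53 ± 0.57. None of the 21 passed in edgeR, over all genes or over the list alone. There were 4 higher and 2 lower at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom. Pan-endothelial genes had a median of 0.19 (range -0.0056 to 0.26) over 27 genes (camera adjusted p = 0.761), with Pecam1 at 0.098 ± 0.31 and the VE-cadherin gene Cdh5 at 0.19 ± 0.34. None passed in edgeR over all genes or the list alone (1 higher and 1 lower at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom). Arterial and Notch genes had a median of -0.11 (range -0.47 to 0.020) over 22 genes (camera adjusted p = 0.664), none passing over all genes or the list alone in edgeR. There were 0 higher and 1 lower (Rbpj, -0.68 ± 0.25) at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom. Venous and lymphatic genes had a median of 0.16 (range -0.064 to 0.29) over 13 genes (camera adjusted p = 0.801), and 0 passed over all genes in edgeR. The scavenger receptor gene Stab1 (-0.77 ± 0.20) was lower adjusted over the list alone and with DESeq2, though not with limma-voom.

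Signalling genes of the endothelial-to-haematopoietic transition had a median of -0.29 (range -0.33 to -0.15) over 27 genes (camera adjusted p = 0.182), of which 2 fell, 0 rose and 25 did not pass in edgeR. The 2 were receptor genes of the TGF-beta family, Tgfbr1 (394 ± 15.7 against 719 ± 6.16 CPM, log2 fold change -0.90 ± 0.14, edgeR adjusted p = 0.0415) and Bmpr2 (261 ± 52.9 against 536 ± 8.12 CPM, -1.07 ± 0.19, edgeR adjusted p = 0.0490). Both calls ended after the length and GC correction, where Tgfbr1 stood at -0.48 ± 0.14 and Bmpr2 at -0.50 ± 0.16, about as uncertain as before but smaller. Adjusted over the list alone 4 were lower, and 4 with DESeq2 and 3 with limma-voom. Lef1, a transcription factor of the Wnt pathway, stood at -1.40 ± 0.30 with an edgeR adjusted p of 0.0843.

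Markers of other cell types did not pass as lists. Erythroid genes had a median of 0.65 (range -0.31 to 0.72) over 16 genes (camera adjusted p = 0.525). The embryonic globin genes Hba-x (1.01 ± 0.24) and Hbb-y (0.73 ± 0.20) were higher adjusted over the list alone and not over all genes (edgeR adjusted p = 0.111 and 0.160). Macrophage and myeloid genes had a median of 1.17 over 11 genes (camera adjusted p = 0.170). This value moved with the setting, to 0.28 without Runx1 replicate 1, 0.13 without Runx1 replicate 2 and 2.11 after thinning (chosen after seeing the data), where the list passed (camera adjusted p = 0.0464). The complement gene C1qa, with 12 and 27 counts against 0 and 0, was higher over the list alone. The receptor gene Csf1r (78.0 ± 93.5 against 11.1 ± 1.99 CPM) differed mainly in 1 library. Megakaryocyte genes had a median of -0.062 (range -0.35 to 0.36) and a mean of 0.44 over 11 genes, with camera pointing up (adjusted p = 0.801). The chemokine gene Ppbp, with 21 and 23 counts against 1 and 0, was higher adjusted over the list alone. Mesenchymal and somite genes had a median of 0.41 (range 0.058 to 0.52) over 18 genes (camera adjusted p = 0.140), and neural genes a median of 0.48 (range 0.071 to 0.53) over 15 genes (camera adjusted p = 0.620). Epithelial and gut genes had a median of -0.30 (range -0.62 to -0.059) and a mean of 0.17 over 13 genes, with camera pointing up (adjusted p = 0.948). In these 6 lists no gene passed over all genes in edgeR. At an unadjusted p under 0.05 there were 4 higher and 1 lower erythroid, 3 and 0 macrophage, 1 and 0 megakaryocyte, 3 and 2 mesenchymal, 2 and 3 neural, and 1 and 0 epithelial genes. DESeq2 called 2 erythroid and 1 macrophage gene higher and 1 neural gene each way, and limma-voom 1 neural gene each way. Over the list alone 1 neural gene was higher (Nefm, 1.48 ± 0.36) and 1 lower (Sox11, -0.52 ± 0.12), and 0 mesenchymal and 0 epithelial genes passed.

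Among RNA classes and nuclear regulators, long non-coding RNAs had a median of -0.22 (range -0.22 to 0.059) over 24 genes (camera adjusted p = 0.324). Of these H19 rose, 0 fell and 23 did not pass, and only H19 passed over the list alone (1 higher with DESeq2 and 1 with limma-voom). Malat1, an abundant nuclear RNA, stood at 291 ± 14.8 against 191 ± 48.5 CPM (0.58 ± 0.23, edgeR adjusted p = 0.309), and Neat1, the scaffold of paraspeckles, at 0.095 ± 0.37. Splicing factors divided, with a median of -0.11 (range -0.17 to -0.072), a mean of 0.0054 and camera pointing down over 46 genes (adjusted p = 0.761). None of the 46 passed over all genes in edgeR (9 higher and 10 lower at an unadjusted p under 0.05, 4 and 7 with DESeq2, 2 and 2 with limma-voom). Over the list alone 6 were higher and 9 lower, led by Luc7l3 (0.76 ± 0.14) and Rbm25 (0.47 ± 0.11) above and Tra2a (-0.71 ± 0.15) and Srsf1 (-0.75 ± 0.16) below 0. Chromatin regulators had a median of -0.15 (range -0.20 to 0.11) over 47 genes (camera adjusted p = 0.459). The histone methyltransferase gene Nsd1 fell (-0.88 ± 0.13, edgeR adjusted p = 0.0346, or -0.48 ± 0.13 and not called after the length and GC correction), 0 rose, 46 did not pass, and 3 were lower adjusted over the list alone. DESeq2 called 1 higher and 4 lower, and limma-voom 0 and 3. Vessel matrix and adhesion genes had a median of -0.0035 (range -0.083 to 0.11) over 21 genes (camera adjusted p = 0.793). The membrane metalloproteinase gene Mmp14 rose (1.03 ± 0.13, edgeR adjusted p = 0.0210), 0 fell, 20 did not pass, and only Mmp14 was called over the list alone (1 higher and 1 lower with DESeq2, 1 and 0 with limma-voom). Mmp14 stood at 0.80 ± 0.12 after the length and GC correction, narrowly short of the threshold (edgeR adjusted p = 0.0511, or 1.03e-09 to 0.0799 over the settings). Histone genes had a median of 1.01 (range -0.079 to 1.40) over 4 measured genes (camera adjusted p = 0.0589, or 0.0454 to 0.796 over the other settings, passing only after thinning). The list of polymerase III and other structured RNAs had a median of 0.56 (range -1.12 to 0.92) over 2 (camera adjusted p = 0.980). These were Lars2 (1.25 ± 0.87), annotated as protein-coding, and Rn7sk (-0.13 ± 0.37), so the median is not a value for structured RNAs alone. In the histone and structured RNA lists no gene passed in edgeR over all genes or the list alone, with DESeq2 or with limma-voom. The histone gene Hist1h2ao (2.77 ± 1.21) had an unadjusted p under 0.05.

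Counted over whole libraries, some RNA classes took a larger part of the Runx1 libraries, among them classes whose lists did not pass. Ribosomal protein genes took 1.56% and 1.65% of gene counts with the Runx1 antibody and 0.836% and 0.845% with IgG. Mitochondrially encoded mRNAs took a mean of 0.469% against 0.274%, mitochondrial ribosomal RNAs 0.0934% against 0.0464% and haemoglobin genes 0.0725% against 0.0396% (n = 2 and 2). The 10 most abundant genes took 5.13% ± 0.073 of counts with the Runx1 antibody and 3.41% ± 0.044 with IgG. Protein-coding genes took 92.4% and 92.6%, processed pseudogenes 1.28% and 1.03%, and long intergenic RNAs 0.914% and 1.06%. For a single measure, 2 against 2 libraries give no two-sided exact permutation p below 0.333, so this test could call none of these differences.

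The called genes differed in transcript length. The median transcript was 2048.5 bases among the 38 higher genes, 8376 among the 42 lower and 3205 among all tested genes. The median 3′ UTR was 449 bases among the higher and 4274.5 among the lower genes, with a GC content of 51.1% and 43.5%. Among the shortest 4132 genes 24 rose and 1 fell, with a median log2 fold change of 0.32. Among the longest 4132 genes 6 rose and 35 fell, with a median of -0.20. The log2 ratio of a Runx1 over an IgG library changed by -0.17 to -0.18 per doubling of transcript length in the 4 pairs, and by 0.0095 and 0.0027 between libraries of the same antibody. Across genes, which are not independent replicates, Spearman's correlation of the log2 fold change was -0.26 with transcript length and 0.249 with GC content.

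**Figure D3:**
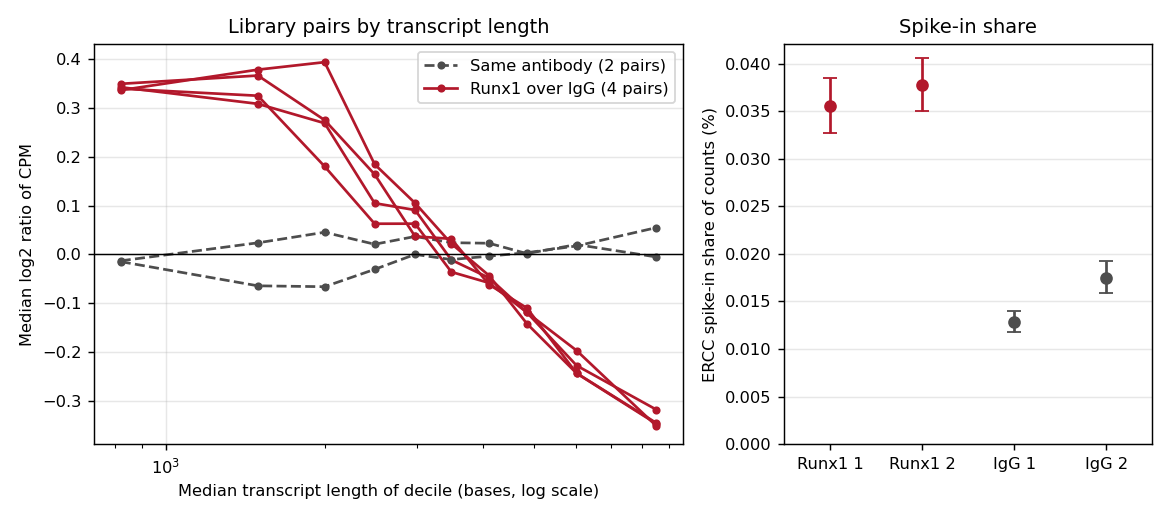
Left, the median log2 ratio of CPM (vertical axis) of 10 groups of genes by transcript length (horizontal log axis, bases), with solid red lines for the 4 pairs of a Runx1 over an IgG library, dashed grey lines for the 2 pairs of the same antibody, and the red lines running from 0.34 to 0.35 at the shortest to between -0.32 and -0.35 at the longest transcripts. Right, the spike-in share of each library's counts (percent) with its exact 95% binomial interval, where both Runx1 libraries lie above both IgG libraries.

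As a descriptive count of RNAs over background, 545 genes had a CPM in both Runx1 libraries at least 2 times that in either IgG library, and 333 genes showed the mirror image. The other 2 ways of splitting the 4 libraries gave 240 and 227 genes, and 219 and 243. Among genes with a mean of at least 10 CPM the counts were 309 and 174, against 80 and 96, and 87 and 81, for the other splits, and at 4 times the background they were 117 and 82. Each of the other splits holds a Runx1 and an IgG library in both groups, so a difference between antibodies lowers its counts.

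Libraries of the same antibody were closer to each other than to the rest among abundant genes. Over the 2381 genes with a mean of at least 100 CPM, Pearson's correlation of log2(CPM + 1) across genes was 0.908 between the Runx1 libraries, 0.942 between the IgG libraries and 0.797 to 0.838 across antibodies. Over all tested genes the Runx1 libraries correlated at 0.829, inside the range of 0.816 to 0.838 across antibodies, and the IgG libraries at 0.878. Replicate counts differed by more than sampling noise, with a chi-square per degree of freedom of 12.02 for the Runx1 and 12.92 for the IgG libraries.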

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

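The tests of the spike-in share were chosen after the shares were seen, and the ERCC spike-ins enter no library size or test of the main comparison. They are used only in the spike-in scaling, an alternative that was also chosen after the data were seen.

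The synthetic spike-in RNAs took a mean of 0.0367% of counts in the Runx1 libraries and 0.0152% in the IgG libraries, a signal outside the gene counts that stood above the level in the control libraries. The shares were 0.0356% (exact 95% binomial interval 0.0328 to 0.0385) and 0.0378% (0.0350 to 0.0406) with the Runx1 antibody, and 0.0129% (0.0117 to 0.0140) and 0.0175% (0.0159 to 0.0192) with IgG. They rest on 596, 713, 494 and 434 counts over 16 to 18 detected spike-ins. Most of these counts came from few spike-ins. The most abundant took 30.1% of them, ERCC-00130 27.5% and ERCC-00096 24.6%, and only the most abundant was left out in the check below.

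That most abundant spike-in is not the cause of the gap, since without it the lowest Runx1 share was still 1.99 times the highest IgG share. With all spike-ins the factor was 2.03, and this value cannot separate uneven addition of spike-ins, a step of addition that differed, and a smaller amount of RNA recovered with the Runx1 antibody: these cannot be told apart, because each would set both Runx1 libraries apart from both IgG libraries and the amounts added are not given in the sources used here. If the spike-ins were added evenly to the recovered RNA, the higher share may mean that the Runx1 pull-downs held less RNA in all than the IgG pull-downs. The scaling to spike-ins, with 91.1% of tested genes below 0 and 3914 called lower, restates this share gene by gene and is no separate evidence for it. A biological difference between the antibodies stays among the open explanations and was not tested.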

How the results depend on the processing

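Thinning, the length and GC correction and the spike-in scaling were chosen after seeing the data; the other alternatives were fixed before the data were examined. The counts of 38 higher and 42 lower genes stayed within 1.5 times with DESeq2 size factors, library totals alone, mitochondrial and haemoglobin genes removed, and thinning. In every fit other than the spike-in scaling, all 38 and all 42 kept their direction wherever they were tested. The strict filter leaves out Tbx15, and the fit with mitochondrial genes removed leaves out mt-Co1 and mt-Rnr2. The counts were 224 and 325 with no low-count filter, 125 and 159 with the strict filter, 246 and 344 with the DESeq2 test, 102 and 120 with limma-voom, 106 and 124 at a threshold of 0.1, 22 and 6 after the length and GC correction, and 19 and 3914 with spike-in scaling. Against a null of 1.5-fold they were 0 and 0 (880 genes at an unadjusted p under 0.05). With each library left out in turn, where the lone library is assumed to vary like the others, 95 to 248 genes were higher and 81 to 352 lower, of which 37 to 38 and 38 to 42 were main calls. The looser threshold and the null of 1.5-fold move the counts by construction; for the others the cause was not tested. Of the 80 calls, 78 had a mean of at least 100 CPM, and after thinning to the smallest library 53 were higher and 57 lower.

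With the replicate block, 2 genes were higher and 0 lower (1566 genes at an unadjusted p under 0.05), Gata2 stood at 0.046 and Runx2 at 0.15, both turned in sign, and 7 of the 8 lists passed. Whether the numbers pair the libraries is not given in the labels. Deviations of same-numbered libraries correlated at 0.0044 across genes, and 2 pairs are too few for this value to settle it.

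Of the 8 lists, 0 passed with an estimated correlation (2 lists at an unadjusted p under 0.05), 2 with fry, 4 after the length and GC correction and 4 to 7 with a library left out; 0 lists were lower in any setting. The count of genes at 2 times the background, 545 and 333, was 117 and 82 at 4 times and 309 and 174 with a mean of at least 10 CPM.

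The spike-in scaling moves most genes almost alike. With it 6 of the 38 higher genes stayed above 0, with 0 of the 38 called higher. All 8 passing lists had medians below 0, yet relative to the median gene these lists stayed at 0.34 to 0.81. In the other settings, results that turned had not passed in the main test. For lists, where the direction is that of camera, the epithelial median was -0.41 with no filter, -0.44 with the strict filter, -0.25 after thinning, -0.29 after the length and GC correction and -0.62 to -0.059 with a library left out. Polymerase III and structured RNAs stood at -1.12 with no filter, 0.41 after thinning, 0.29 after the correction and -0.55 to 0.92 with a library left out. Megakaryocyte genes stood at -0.067 with the strict filter. After the length and GC correction, the RUNX and CBF beta list stood at 0.12, blood transcription factors at -0.052 and chromatin regulators at 0.11, and erythroid genes stood at -0.31 with haemoglobin removed. With a library left out, the RUNX and CBF beta list ran from -0.65 to 0.63, blood transcription factors from -0.089 to 0.095, venous genes from -0.064 to 0.29, megakaryocyte genes from -0.35 to 0.36 and vessel matrix genes from -0.083 to 0.11.

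Among genes with a library left out, Runx2 ran from -0.65 to 0.98, Itgb3 from -0.082 to 1.099, Lars2 from -1.01 to 2.07, H1f0 from -0.053 to 0.68, and Hist1h1c from -0.37 to 0.29. Gata2 ran from -0.41 to 0.50, Pecam1 from -0.069 to 0.26, Cdh5 from -0.012 to 0.41, Kit from -0.94 to 0.16 and Neat1 from -0.21 to 0.44. Runx2 stood at 0.037 with limma-voom, 0.055 after thinning and 0.12 after the length and GC correction. Hist1h1c stood at 0.023 with limma-voom and 0.11 after thinning, H1f0 at -0.033 after the correction, and Gata2 at 0.010 with library totals and 0.094 after thinning. For all of these the cause was not tested. Over the 137 named genes and 30 lists, 1656 and 363 values kept direction and side of the threshold, 81 and 30 lost the call and 160 and 3 gained it.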

Other observations

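In the paragraphs below, Fisher's exact test and the length and GC correction were chosen after the results were seen.

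Several called genes outside the rule for named genes were picked after their values were seen. Of the genes higher with the Runx1 antibody, Cct7, a subunit of the chaperonin that folds actin and tubulin, rose 2.02-fold, the cohesin gene Smc1a 1.98-fold, the ABC protein gene Abcf1 1.89-fold and the high-mobility-group gene Hmgb2 1.57-fold. Of the genes lower with it, the log2 fold change was -1.16 for the Wnt co-receptor gene Lrp6, -1.12 for the p53 regulator gene Mdm4, -1.07 for the tumour suppressor gene Apc and -0.97 for the Frizzled receptor gene Fzd3, with edgeR adjusted p from 0.0138 (Lrp6) to 0.0481 (Apc). Smc1a and Hmgb2 were still called after the length and GC correction and the others were not, with Cct7 at 0.71 ± 0.16, Abcf1 at 0.66 ± 0.14, Lrp6 at -0.79 ± 0.13, Mdm4 at -0.73 ± 0.15, Apc at -0.60 ± 0.18 and Fzd3 at -0.36 ± 0.16. Under the spike-in scaling 6 of the 38 higher genes stayed above 0, with 0 of the 38 called higher. All 42 lower genes stayed below 0.

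The ribosomal protein genes were higher with the Runx1 antibody relative to other genes, with a median log2 fold change of 0.83 over 80 genes (under the spike-in scaling -0.44, or 0.81 relative to the median gene), a call that is lost with an estimated correlation (camera adjusted p = 0.296). Length and GC content, as fitted here, do not account for all of this pattern. The median after the correction was 0.52 with a lower bound of 0.351. In thinned libraries the lower bound was 0.801. Random thinning keeps each gene's expected part of a library, so the median could hardly fall. This value therefore cannot exclude causes that go with depth. Reads shared with pseudogene copies do not account for the pattern in the 6 genes of this list with no near-identical copy. Their median was 1.22 with a lower bound of 0.539, although 6 genes are few and the other 74 have copies. These lower bounds come from draws over genes and leave out the spread between libraries. After the correction the fold was smaller, and part of the pattern may follow transcript length, also where the fit corrects too little. A difference between the antibodies in the RNA they hold, or between the bead preparations in the RNA that sticks to them, stays open and was not tested.

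Longer transcripts were lower with the Runx1 antibody. The largest slope between libraries of the same antibody was 0.0568 times the smallest of the 4 slopes between antibodies. Variation of the size seen between these replicates therefore does not account for the pattern. Each antibody had a single such pair, whose replicates may be technical, so larger variation between preparations is not excluded. Thinned libraries kept 0.979 of the slope. Random thinning keeps each gene's expected part of a library, so this value cannot exclude causes that go with depth. Fragmentation of RNA during the pull-down, a preference of the antibody or the beads, and a difference in reverse transcription between the pairs of libraries would each give both Runx1 libraries a shared slope, and were not tested here. With 2 libraries per antibody, a batch that coincides with the antibody could have the same effect, and the labels give no batch.

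After the length and GC correction, genes with runs of A in their coding sequence stood out among those called higher, which led to a hypothesis that oligo-dT priming inside A-rich coding stretches contributes to the difference. In the test fixed for it, 798 coding genes with at least 15 A in some 20 bases had a median corrected log2 fold change 0.0796 above that of 9883 other coding genes (95% bootstrap interval 0.0308 to 0.139), which spans the bound of 0.1 set for it and leaves the question open. Over the coding genes with a mean of at least 100 CPM the corrected difference was 0.114 (0.0462 to 0.175), which spans that bound too. Before the correction the difference over all coding genes was -0.13 (-0.18 to -0.065), so its direction depends on the correction. Among coding genes with a mean of at least 100 CPM, 12 of the 21 higher after the correction were A-rich (57.1%), among them Eif5b, Ccdc34, Ppig and Luc7l3, against 326 of 2224 others (14.7%; odds ratio 7.75, 95% interval 2.97 to 21.0, two-sided Fisher's exact p = 9.19e-06). This test was run on the genes in which the pattern was noticed. Their calls came from the correction, which itself turned the A-rich difference from below to above 0, so this test does not stand apart from it. Of the 12, Ppig, Luc7l3, Esf1, Tpr and Rbm25, picked after their values were seen, had not been called before the correction (edgeR adjusted p = 0.0565 to 0.0984). Before the correction 10 of 34 higher and 3 of 41 lower genes were A-rich (Fisher's exact p = 0.0273 and 0.191; 4 such tests were run), and the 5 genes lower after the correction held 0.

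The other 2 ways of splitting the 4 libraries gave 0 and 0 genes with edgeR (336 and 312 at an unadjusted p under 0.05), and 0 and 0 with DESeq2 and with limma-voom, against 80 for the real split. Each of those splits holds a Runx1 and an IgG library in both groups. A difference between antibodies then widens the spread within groups and lowers the calls, so these are not counts of false calls. With 3 splits in all, a share under 0.05 cannot be reached.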
